A study of Homo sapiens with 3 samples.

How the data were processed

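Gene expression was measured on 3 Affymetrix arrays of the human multiple myeloma cell line MM1S, 1 array per group. The groups were untreated cells, cells cultured with 10 nM FK866 for 6 h and cells cultured with it for 24 h. Per the labels' protocols, biotinylated cRNA was made from 1 µg of total RNA with the standard Affymetrix procedure. The deposited table gives 1 intensity on a linear scale per probe set and array, from 0.1 to 20258. How the probes were summarised, the background corrected and the arrays scaled to each other is not given in the sources used here. Detection calls were not used here. The median deposited intensity was 20.4 in the untreated array, 17.4 at 6 h and 17.2 at 24 h, so the values did not share one distribution. The number of arrays limits the precision of every value.

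The table holds 54675 probe sets, 62 of them Affymetrix controls. GEO's platform annotation, dated 2016, gave exactly 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. Of those with 1 symbol, 41043 matched a gene of the RefSeq annotation by gene identifier, and 0 symbols needed updating. A probe set with several symbols or none gives no gene a value here. No coordinates are given, because the array table names no genome build.

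Signals below 16 were set to this floor, and log2 values were taken. A linear table had been foreseen, with this floor. A probe set was kept when its mean log2 value over the 3 arrays was at or above the median of all probe sets other than controls, which equals a signal of 19.1. This kept 27308 probe sets, of which 22601 had 1 symbol and named 11883 genes. A gene has the value of its kept probe set with the highest mean, and 5967 genes had several. Differences are log2 differences between 2 arrays, and a fold is 2 to the power of their size. A fold against a value at the floor is a lower bound.

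With 1 array per group no test was run, and no difference has a replicate check. Genes are described by a fixed size, at least 2-fold. Each of 24 gene lists is described by the percentile of its median log2 difference among 10000 random lists of as many genes, matched on mean log2 value in 20 bins. A list is said to stand apart below percentile 2.5 or above 97.5, which describes these arrays only. Lists with under 5 measured genes have no percentile. A measured gene is one with a kept probe set.

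The spread between probe sets of the same gene is the only error measure within the series. It covers probe error and isoforms, not variation between cultures. Its pooled SD on the log2 scale was 0.38 in each comparison with untreated cells and 0.34 between the treated arrays. At 6 h it was 0.61 for genes with a mean signal under 32 and 0.13 for those of 1024 or more, and at 24 h 0.59 and 0.14.

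The lists, the size, the filter, most of the alternatives and the rule for named genes were set before the data were examined. That rule takes the 10 highest and 10 lowest genes in each comparison with untreated cells, and 5 each way between the treated arrays, among genes whose kept probe sets all differ in the same direction. A further condition, both arrays above the floor, was added once the table proved linear, because values at the floor have no order. The rule also takes the 3 highest and 3 lowest members of each list at each time, every measured gene of NAD metabolism, and ATF4, DDIT3, MYC, IRF4, CDKN1A, TFEB, SQSTM1, MAP1LC3B, DUSP6, MCL1, BCL2L11 and HSPA5.

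The procedure was tested on simulated data whose noise was the probe set spread. In the simulated 6 h comparison of 12082 genes, 93.9% of genes lowered 4-fold and 80.0% of genes raised 2.83-fold reached 2-fold, as did 2.38% of unchanged genes. In the simulated 24 h comparison of 12097 genes, 97.5% of genes raised 4-fold and 84.2% of genes lowered 2.83-fold did, with 2.32% of unchanged genes. At a mean log2 signal of at least 8, 0 of 5440 unchanged genes reached 2-fold in the simulated 6 h comparison and 0 of 5455 in the 24 h one. Of 100 unchanged lists of 25 genes, 6 and 4 stood apart in the simulated 6 h and 24 h comparisons. These genes were drawn at random and their noise was independent, unlike lists of related genes.

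Alternatives covered the scaling (quantile normalization, centring on array medians), the filter, the floor, the summary of several probe sets, probe sets that may cross-hybridise, the size, and the summary and matching of lists. Counts restricted to genes above the floor on both arrays or to a mean log2 signal of at least 8, the latter also after quantile normalization, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.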

Results

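Transcript levels were measured in MM1S, an established human multiple myeloma cell line, without and with FK866. This compound inhibits NAMPT, the rate-limiting enzyme that recycles nicotinamide into NAD. Untreated cells, labelled as 0 h, and cells given 10 nM FK866 for 6 h or 24 h each gave 1 array. The comparisons ask how transcript levels under NAMPT inhibition differed from untreated cells early and late, and between the treated arrays. With 0 untreated arrays at a treated time, no comparison can tell FK866 apart from fresh medium, serum or time in culture. Signals are in arbitrary units, and no difference has a replicate check.

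The arrays differed in overall level. The median gene differed from untreated cells by a log2 value of -0.10 at 6 h and -0.13 at 24 h, and the differences below are to be read against these shifts. Hybridisation spikes with a mean log2 signal of at least 8 had median differences of -0.16 at 6 h and -0.19 at 24 h, lower in 12 of 12 probe sets each time. Poly-A spikes of that level, which pass through the labelling, had median differences of -0.30 at 6 h and 0.25 at 24 h. The log2 difference between 3' and 5' probe sets, a sign of RNA quality, was 0.24, 0.20 and 0.32 for GAPDH and 2.25, 2.55 and 2.33 for ACTB in the untreated, 6 h and 24 h arrays.

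At 6 h, the lowest genes included NAMPT itself, regulators of cAMP and MAP kinase signalling, and an enzyme of sterol synthesis. NAMPT was 4.38-fold lower, with a signal of 5473 in untreated cells and 1248 at 6 h, and its 4 probe sets lay between -2.43 and -0.88 on the log2 scale. CREM, a transcription factor of the cAMP response, was 5.06-fold lower (2973 to 587), but its 5 probe sets ranged from -2.41 to -0.30, and it was not 2-fold lower without probe sets that may cross-hybridise. PDE4B, a phosphodiesterase that degrades cAMP, was 4.04-fold lower, and DUSP4, a MAP kinase phosphatase, 3.89-fold lower (2919 to 750). The AP-1 member FOSL2 was 5.43-fold lower. HIVEP1, a zinc finger factor, was 5.22-fold lower, with its second probe set at -0.22. SQLE, the squalene epoxidase of cholesterol synthesis, was 4.34-fold lower (239 to 55.1). SPIDR, IFFO2 and TP53INP2 were 4.64-fold, 4.39-fold and 4.35-fold lower.

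The 10 highest genes at 6 h were mostly dim in untreated cells. FRMD6 was 3.61-fold higher (258 to 929) and the transporter family member SLC16A14 3.50-fold higher (145 to 506). MLLT3, a subunit of the super elongation complex, was 3.82-fold higher (68.6 to 262). PHF21A, part of a histone demethylase complex, was 3.73-fold higher, though not 2-fold higher without probe sets that may cross-hybridise. METTL15 was 3.42-fold higher. MPPED2 was 10.6-fold higher but had an untreated signal of 16.6, next to the floor. HTR2C, CRACD and FHIP1A were 3.71-fold, 3.52-fold and 3.51-fold higher and ESRRG 4-fold higher, with untreated signals from 16.8 to 21.3. With a floor of 64, these 4 genes, IFFO2 and SPIDR no longer differed 2-fold.

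**Figure D1:**
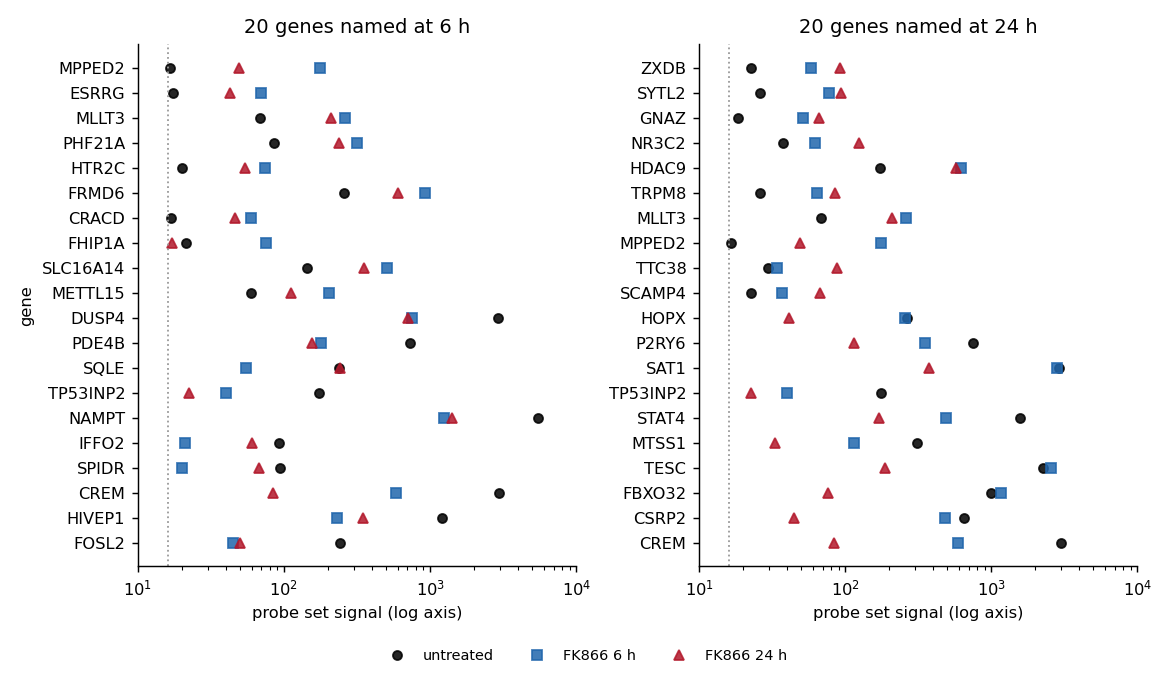
Probe set signal (log axis, arbitrary units) of the 20 genes named at 6 h (left) and the 20 named at 24 h (right) in the untreated (circles), FK866 6 h (squares) and FK866 24 h (triangles) arrays, 1 array each; the dotted line is the floor of 16. NAMPT lies at 5473 in untreated cells and at 1248 and 1422 in the treated arrays, and most of the higher genes start near the floor.

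Of 11883 genes, 171 were at least 2-fold higher and 395 at least 2-fold lower at 6 h, together 4.76%. Probe set noise alone took 2.38% of unchanged genes past 2-fold in the simulated 6 h comparison. That simulation had no level difference between arrays and no variation between cultures, so 2.38% is no background rate for these arrays. The balance depended on the scaling: quantile normalization gave 280 higher and 208 lower, and centring on array medians 273 and 226, whereas subtracting the median gene difference left 228 higher and 271 lower. Among 5530 genes with a mean log2 signal of at least 8, 23 were higher and 61 lower, and 33 and 38 after quantile normalization. Where a gene had several kept probe sets, all of them reached 2-fold for 5 of 71 higher and 38 of 135 lower genes.

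Genes of sterol and fatty acid synthesis were lower as a group at 6 h. Of 21 measured members, 20 lay below the median of all genes, 5 were at least 2-fold lower and 0 at least 2-fold higher. Their median difference was -0.60, below all 10000 matched random lists, whose central 95% ran from -0.23 to 0.02. Besides SQLE, INSIG1, which restrains the SREBP transcription factors, was 3.47-fold lower (6652 to 1918). SCD, a fatty acid desaturase, was 2.51-fold lower, HMGCS1, an early enzyme of the mevalonate pathway, 2.49-fold lower, and the isomerase IDI1 2.32-fold lower, with 1 of its 4 probe sets at 0.05. By the mean over probe sets, SCD and IDI1 were not 2-fold lower.

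Genes of G2 and mitosis were higher as a group at 6 h. Of 36 members, 31 lay above the median of all genes, and the list median of 0.28 exceeded all 10000 random lists (central 95% from -0.19 to -0.03). The differences were small: the kinetochore motor CENPE, 2.23-fold higher, was the only member past 2-fold. The phosphatase CDC25C differed by 0.92 and the kinase NEK2 by 0.71, and CCNA2 (-0.38) and KIF2C (-0.37) were the lowest. The S phase list had a median of -0.16 (percentile 7.17) and stood apart after quantile normalization (percentile 2.42) and with the list mean (1.96), with CCNE2 2.05-fold and E2F1 2.02-fold lower, but neither 2-fold after quantile normalization. Heat shock genes had a median of 0.04 (percentile 99.2), with BAG3 at 0.55, DNAJB1 at 0.54 and 0 of 17 past 2-fold. Only 17 of 23 listed genes were measured, and probe sets assigned to several genes count for none. The probe set assigned to both HSPA1A and HSPA1B, which are listed, had signals of 213 in untreated cells, 1026 at 6 h and 79.6 at 24 h. The position of the heat shock list was lost with a filter at the 75th percentile and without probe sets that may cross-hybridise.

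Targets of ATF4, the effector of the integrated stress response, were lower as a group at 6 h. Their median was -0.33 over 29 genes (percentile 0.01), with 3 members at least 2-fold lower. CTH, a cysteine-producing enzyme, differed by -1.32, ALDH1L2 by -1.12 and the cystine transporter SLC7A11 by -1.10. ALDH1L2 and SLC7A11 were not 2-fold lower after quantile normalization, nor CTH by the mean over probe sets. ATF4 itself differed by -0.23 and DDIT3 by 0.11. Endoplasmic reticulum chaperones and targets of XBP1 and ATF6 had a median of -0.19 over 28 genes (percentile 0.67). There SEC24D was 2.39-fold lower, EDEM1 differed by -0.65, DNAJB9 by -0.64 and the chaperone HSPA5 by -0.22. Neither list stood apart with the mean over probe sets, nor did the ATF4 list without probe sets that may cross-hybridise.

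Transcripts that report ERK activity had a median of -0.37 over 14 genes at 6 h (percentile 0.60), with DUSP4 the only member past 2-fold and DUSP6, a feedback phosphatase of ERK, 1.49-fold higher. NF-kB targets had a median of -0.38 over 16 genes (percentile 0.53), with CXCL10 2.42-fold, CCL4 2.40-fold and REL 2.37-fold lower (REL not 2-fold with log2(signal + 32)) and TNFAIP8 at 0.47. Both lists lost this position without the filter on level, with a filter at the 75th percentile and with the list mean, and the ERK list also with the mean over probe sets. In all, 7 of 23 lists stood apart at 6 h. Lists of unrelated genes would give 1.15, but members of a list may move together between any 2 arrays. The 1.15 is therefore no chance level for these lists.

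**Figure D2:**
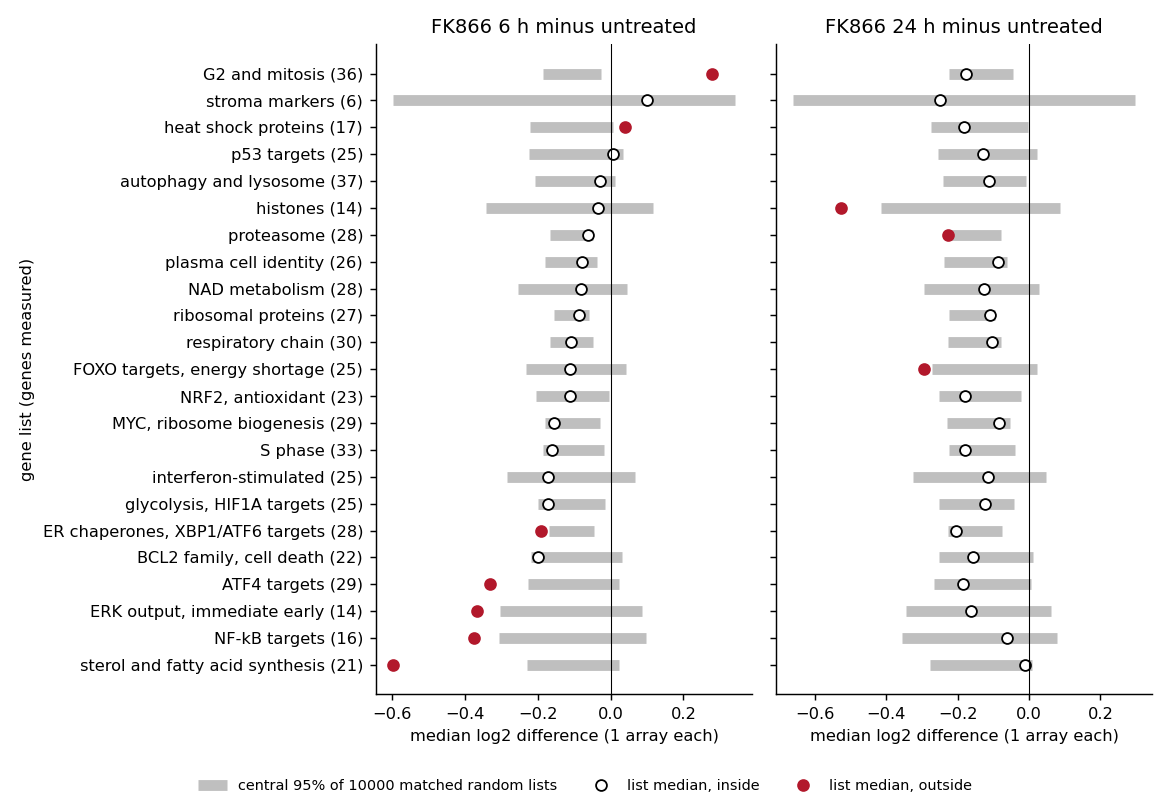
Median log2 difference from the untreated array of 23 gene lists at 6 h (left) and 24 h (right), 1 array each; circles are list medians, filled where they lie outside the central 95% of 10000 random lists matched on level (grey bars), and numbers in brackets are measured genes. At 6 h sterol and fatty acid synthesis lies at -0.60 and G2 and mitosis at 0.28, and at 24 h histones lie at -0.53.

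At 24 h, NAMPT was still 3.85-fold lower than in untreated cells, and several bright genes that had been close to their untreated level at 6 h were far lower. TESC, a calcium-binding protein, differed by -3.59 (2266 to 188), and SAT1, which acetylates polyamines, was 7.75-fold lower (2904 to 375), with 3 probe sets between -3.48 and -2.95. FBXO32, a ubiquitin ligase subunit, differed by -3.70 (988 to 76.1), with 6 probe sets between -4.25 and -2.44, although at 6 h these had ranged from -2.51 to 0.24. CREM was 35.5-fold lower by its brightest probe set (2973 to 83.7), its 5 probe sets ranged from -5.15 to -0.79, and it was not 2-fold lower without probe sets that may cross-hybridise. STAT4, a cytokine-activated transcription factor, was 9.20-fold lower (1571 to 171) and the nucleotide receptor P2RY6 6.49-fold lower. CSRP2, MTSS1, TP53INP2 and HOPX were 14.6-fold, 9.35-fold, 7.76-fold and 6.40-fold lower.

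Of the 10 highest genes at 24 h, the histone deacetylase HDAC9 was 3.28-fold higher (173 to 569), but its second probe set differed by 0.15, and the mean over probe sets did not reach 2-fold. MLLT3 was 3.05-fold and NR3C2, the mineralocorticoid receptor, 3.32-fold higher (37.4 to 124). ZXDB, SYTL2, GNAZ, TRPM8, MPPED2, TTC38 and SCAMP4 were 2.94-fold to 4.06-fold higher from untreated signals between 16.6 and 29.5. With a floor of 64, these 7 genes and NR3C2 no longer differed 2-fold.

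At least 2-fold differences at 24 h numbered 135 genes higher and 495 lower, together 5.30%. In the simulated 24 h comparison, 2.32% of unchanged genes passed 2-fold, again with no level difference between arrays and no variation between cultures. Quantile normalization gave 287 higher and 264 lower, and centring on array medians 304 and 265, whereas subtracting the median gene difference left 215 higher and 335 lower. Among the genes with a mean log2 signal of at least 8, 15 were higher and 86 lower, and 27 and 63 after quantile normalization. All probe sets reached 2-fold for 11 of 56 higher and 60 of 183 lower genes with several.

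Histone genes were lower as a group at 24 h, with 13 of 14 below the median of all genes and a list median of -0.53 (percentile 0.46). H4C8 was 2.70-fold lower, H2BC21 2.49-fold lower, and H2AC8 at least 2.02-fold lower, its 24 h signal lying under the floor. H1-4 differed by -0.04. With a floor of 64, H4C8, H2BC21 and H2AC8 were not 2-fold lower. The list's position was lost without probe sets that may cross-hybridise. FOXO targets and genes of energy shortage had a median of -0.29 over 25 genes (percentile 1.25), with 6 at least 2-fold lower, among them GABARAPL1 (3.42-fold), BCL6 (3.15-fold), ARRDC3 (2.99-fold) and CITED2 (2.32-fold); BCL6 was not 2-fold lower with a floor of 64. The proteasome list had a median of -0.23 over 28 genes (percentile 2.21), with PSMC1 lowest at -0.51. The FOXO list lost its position under 4 of 8 alternatives and the proteasome under 5 of 8, quantile normalization among them in both cases. In all, 3 of 23 lists stood apart at 24 h. Sterol synthesis (percentile 95.7) did so on the higher side and NF-kB targets (73.6) on the lower side without probe sets that may cross-hybridise (98.9 and 0.03) and with the list mean (98.7 and 1.75). The S phase list (14.6) did so with the mean over probe sets (1.91).

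In the list of NAD metabolism, NAMPT was the only one of 28 measured genes that differed 2-fold at either time, and the list did not stand apart (medians -0.08 and -0.13, percentiles 59.9 and 51.0), except on the lower side at 6 h with a filter at the 75th percentile (percentile 0.12). NMRK1, the nicotinamide riboside kinase, was 1.65-fold lower at 6 h and 1.44-fold lower at 24 h. KMO, of the kynurenine pathway, was 1.75-fold higher at 24 h, with its 3 probe sets between 0.81 and 0.96. SIRT5 differed by 0.79 at 24 h with its other probe set at -0.95. NAPRT, which starts NAD synthesis from nicotinic acid, had an untreated signal of 62.0 and differed by -0.19 and 0.31. The NAD-consuming enzymes PARP1 (-0.13 and 0.14), CD38 (0.09 and -0.44) and SIRT1 (-0.40 and -0.24) lay within 2-fold. QPRT at 24 h and HAAO in untreated cells lay under the floor.

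Genes of autophagy and the lysosome did not stand apart (medians -0.03 and -0.11, percentiles 89.4 and 55.3), except on the higher side at 6 h with a filter at the 75th percentile (percentile 99.0). SQSTM1, the autophagy receptor p62, was 2.02-fold lower at 6 h and 2.45-fold lower at 24 h by its brightest probe set, but its 5 probe sets ranged from -1.02 to 0.33 and from -1.30 to 0.00, and their mean did not reach 2-fold. TFEB, a regulator of lysosomal genes, differed by 0.35 and 0.28, MAP1LC3B by -0.13 at 24 h, and the lysosomal galactosidase GLA was 2.83-fold lower at 24 h. p53 targets had medians of 0.01 and -0.13 (percentiles 94.0 and 41.9) and stood apart at 6 h after quantile normalization (percentile 99.3) and with a filter at the 75th percentile (98.5). CDKN1A differed by -0.35 and -0.01. In the BCL2 family and cell death list (medians -0.20 and -0.16, percentiles 4.80 and 29.0), the pro-apoptotic BCL2L11 was 1.76-fold and 1.82-fold lower with 7 of 7 probe sets negative. This list stood apart on the lower side without probe sets that may cross-hybridise (percentiles 0.07 and 1.04). BMF was 2.18-fold lower at 24 h, but not 2-fold after quantile normalization, and MCL1 differed by -0.07 and -0.60.

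Plasma cell identity genes did not stand apart (medians -0.08 and -0.09, percentiles 75.5 and 91.2). IRF4, a transcription factor of plasma cells, was 1.90-fold higher at 24 h (1698 to 3226), with its 2 probe sets at 0.82 and 0.93. XBP1 differed by -0.56 and -0.79, and MYC by 0.16 and -0.16. Genes of ribosomal proteins (-0.09 and -0.11), the respiratory chain (-0.11 and -0.10), glycolysis and hypoxia (-0.17 and -0.12) and MYC targets of ribosome biogenesis (-0.15 and -0.08) had list medians inside their random ranges at 6 h and 24 h. So did NRF2 and antioxidant genes (-0.11 and -0.18) and interferon-stimulated genes (-0.17 and -0.11), where IFITM1 was 2.34-fold and 3.60-fold lower, but not 2-fold with a floor of 64. Of these, ribosome biogenesis stood apart at 6 h without probe sets that may cross-hybridise (percentile 0.38), and the respiratory chain at 24 h with the list mean (98.2). Stroma markers (6 of 19 measured, medians 0.10 and -0.25) did not stand apart, and of 21 markers of myeloid, T and NK cells only 3 were measured, with medians of 0.74 and 0.03 and no percentile.

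Between the treated arrays, sterol synthesis genes were higher and G2 and mitosis genes lower at 24 h than at 6 h. The sterol list had a median of 0.75 (above all 10000 random lists), with 7 of 21 members at least 2-fold higher. SQLE was 4.37-fold higher, with 24 h and untreated signals of 241.0 and 239, but not 2-fold by the mean over probe sets. HMGCS1 was 3.79-fold higher, to 1416 against 929 in untreated cells, whereas SREBF1 was still 2.16-fold lower than untreated at 24 h, but not 2-fold after quantile normalization. The mitosis list had a median of -0.44 (below all random lists), with 35 of 36 members negative, and its median against untreated cells at 24 h was -0.18, inside its random range of -0.22 to -0.04. TRMT44, TUBB2B and SPIDR were 4.60-fold, 3.64-fold and 3.33-fold higher, but not 2-fold with a floor of 64. FBXO32, TESC, CSRP2, SAT1 and CREM were 15.4-fold, 13.5-fold, 10.7-fold, 7.50-fold and 7.02-fold lower, CREM not 2-fold without probe sets that may cross-hybridise.

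In this comparison 10 of 23 lists stood apart. On the higher side, sterol synthesis was joined by ATF4 targets (median 0.13), glycolysis and hypoxia (0.10), ribosome biogenesis (0.09) and the respiratory chain (0.06). The ATF4 list lost this position with the list mean (percentile 96.9), glycolysis and hypoxia without the filter on level (92.8) and the respiratory chain without probe sets that may cross-hybridise (90.1). On the lower side, mitosis was joined by histones (-0.52), FOXO targets (-0.27), heat shock genes (-0.22) and the proteasome (-0.14). Genes of autophagy and the lysosome (percentile 4.72) stood apart on the lower side with the mean over probe sets (0.43), and ribosomal proteins (88.4) on the higher side with 50 bins (98.0). DNAJB4, a heat shock cochaperone, was 3.34-fold lower. At least 2-fold differences numbered 130 genes higher and 219 lower (quantile normalization, 172 and 198; centring on array medians, 158 and 170; subtracting the median gene difference, 146 and 183). A list that differed at 6 h and returned by 24 h owes both differences to the single 6 h array.

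**Figure D3:**
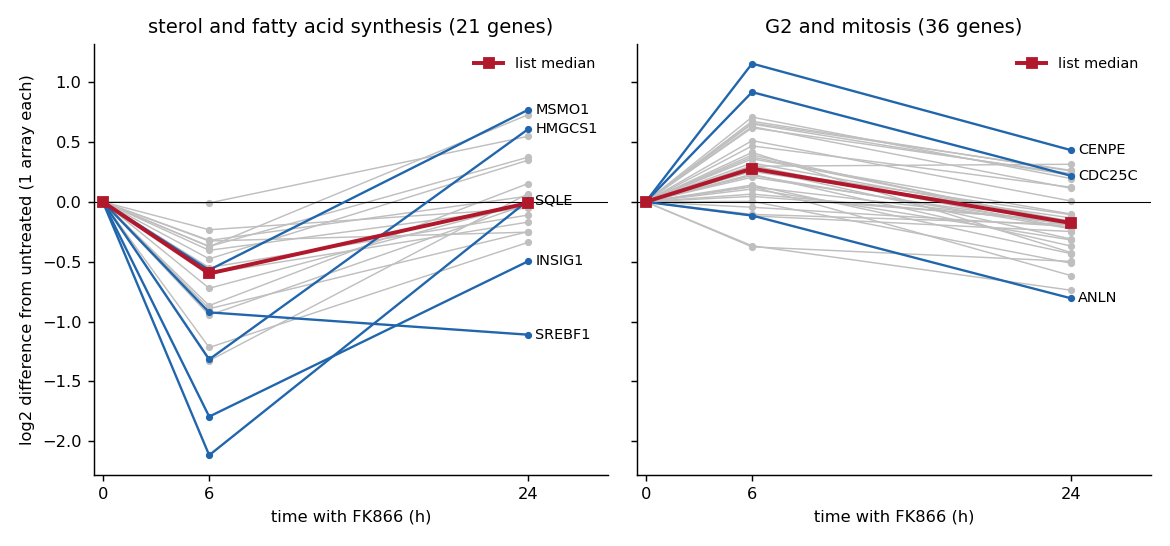
Log2 difference from the untreated array against time with FK866 (h) for the 21 measured genes of sterol and fatty acid synthesis (left) and the 36 of G2 and mitosis (right), 1 array per time; thin lines are genes, some named, and squares the list median. The sterol median is -0.60 at 6 h and -0.01 at 24 h, and the mitosis median 0.28 and -0.18.

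The differences at 6 h and 24 h correlated across genes with r = 0.60, where genes are not independent replicates. Both share the untreated array: shuffling each gene's 3 values among the arrays gave a mean r of 0.50 (0.47 to 0.53 in 100 shuffles). The covariance was 0.129 against 0.105 after shuffling. At both times 191 genes were at least 2-fold lower, against 83.9 after shuffling and 16.5 for independent lists, and 52 were higher, against 68.9 and 1.94. Shuffling keeps the differences among a gene's 3 values and spreads the level shift over the arrays, so its counts are no noise level. The median gene was lower in both treated arrays, which favours an overlap of lower genes over one of higher genes. All of the overlap of higher genes may come from the shared untreated array. The untreated array cannot be split, so part of the overlap of lower genes may come from it too. A 2-fold difference in opposite directions was seen for 1 gene.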

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

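None of the differences between 6 h and 24 h given here was tested, since each time has 1 array, and the sizes that singled them out were chosen after seeing the data. The tests of dim probe sets and of time in culture were also chosen after the result was seen; those of scaling and of unnamed probe sets were set before.

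The median of the sterol and fatty acid synthesis genes lay on opposite sides of the median of matched random lists at the 2 times, by -0.50 at 6 h and 0.12 at 24 h. It was below all random lists at 6 h but inside their central range at 24 h (-0.01, range -0.28 to 0.01, percentile 95.7). After quantile normalization the list median at 6 h was -0.43, below the central random range of -0.11 to 0.16. This cannot decide on scaling as a source, because scaling moves a list and its level-matched random lists alike. Noise of dim probe sets is argued against. The 12 members with a mean log2 signal of at least 8 had a median of -0.72 (range -0.25 to 0.02). FK866 cannot be told apart from fresh medium, serum or time in culture, because 0 untreated arrays were taken at a treated time. A transient response to FK866 therefore stays a hypothesis, and it rests on the single 6 h array.

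The list of MYC and ribosome biogenesis lay -0.056 at 6 h and 0.056 at 24 h from the median of its random lists, inside their central range both times (percentiles 8.14 and 89.2). The proteasome list lay 0.039 and -0.078 from theirs, inside the range at 6 h (percentile 92.8) and below it at 24 h (2.21). Among single genes, the log2 difference from untreated cells had opposite signs for BAG3 (0.55 at 6 h, -0.45 at 24 h), DNAJB1 (0.54 and -0.85), HMGCS1 (-1.32 and 0.61), MSMO1 (-0.57 and 0.77) and PFKM (-0.43 and 0.50).

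Probe sets without a gene symbol, which no comparison above uses, also differed. With both arrays above the floor, 23 were at least 2-fold higher and 274 lower at 6 h, and 24 higher and 308 lower at 24 h. Of 3605 kept, 12.9% were at least 2-fold lower at 24 h and 11.4% at 6 h. In 100 draws of named probe sets matched on level, 5.38% to 8.02% were lower at 6 h. The low level of probe sets without a symbol thus does not account for the whole share. After quantile normalization the share at 6 h fell from 11.4% to 5.36%, against 2.79% to 4.27% in matched draws. The mean of the matched draws fell as well, from 6.97% to 3.47%. Scaling may thus account for much of the share in both groups, but it left an excess among probe sets without a symbol. No biological explanation was tested. Probe sets assigned to several genes are not used in the lists and counts of genes above either. Of 1102 kept, 15 were at least 2-fold higher and 49 lower at 6 h, and 12 and 78 at 24 h. The probe set of this kind with the largest higher difference at 6 h had signals of 213 in untreated cells, 1026 at 6 h and 79.6 at 24 h. It is assigned to HSPA1A and HSPA1B, which are on the heat shock list but count as not measured there.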

How the results depend on the processing

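No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. The total counts of 2-fold genes stayed within 1.5 times under quantile normalization, centring, the mean over probe sets and without probe sets that may cross-hybridise. The genes themselves and the balance of higher and lower did not stay. Quantile normalization shared 378 of the 566 genes at 6 h and 399 of the 630 at 24 h. Centring shared 397 and 400. Leaving out the filter on level gave identical counts by construction and says nothing about stability. In the order 6 h, 24 h and 24 h against 6 h, the counts were 136, 162 and 62 with a filter at the 75th percentile, 164, 197 and 69 with a floor of 64, and 134, 183 and 68 with log2(signal + 32). They were 2024, 2271 and 1568 at 1.5-fold and 67, 115 and 50 at 3-fold, by construction of the size. Of alternatives chosen after seeing the data, a mean log2 signal of at least 8 gave 84, 101 and 36, and with quantile normalization 71, 90 and 31. Requiring both arrays above the floor gave 419 at 24 h and 211 between the treated arrays. Most 2-fold genes were thus dim. The count of lists standing apart at 6 h was 4 with the mean over probe sets. At 24 h it was 1 with quantile normalization, 1 without the filter and 5 with the list mean; the cause was not tested. The correlation of the times was 0.64 with the filter at the 75th percentile. Of the other values, 464 list medians and 5057 gene differences moved by less than the spread used, and 82 and 748 by more. Part of this was set by construction. Changing the bins leaves each list median as it was, and changing the filter leaves the difference of a measured gene as it was. The tallies are thus no measure of stability. Among called values, only the heat shock median at 6 h changed sign, from 0.04 to -0.01 with the filter at the 75th percentile. That median was still above its random median.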

Other observations

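All tests in this part except that of scaling were chosen after the result was seen, and the cAMP genes were one of several groups looked at after the lowest genes were known. Several genes of cAMP signalling, chosen after their values were seen, were lower at both times. The phosphodiesterases PDE3B, PDE4A and PDE8A differed by -1.05, -1.62 and -1.55 at 6 h and by -2.59, -1.46 and -1.55 at 24 h. RGS1 and RGS2, regulators of G protein signalling, were 2.01-fold and 2.09-fold lower at 6 h and 2.39-fold and 2.62-fold lower at 24 h, from bright untreated signals of 7973 and 3854. KLF4 was 2.99-fold and 4.61-fold lower. The nuclear receptor NR4A3 had a signal of 154 in untreated cells and lay under the floor in both treated arrays. DUSP1 (0.36 and 0.45) and MAFF (0.39 and 0.85) were higher.

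A candidate explanation is lower activity of cAMP-responsive transcription. A list of 33 cAMP-responsive genes was written without those that prompted the idea (CREM, PDE4B, PDE3B, PDE4A, FOSL2 and NAMPT) and before its members' values were looked up. It includes RGS1, RGS2, KLF4, NR4A3, DUSP1 and MAFF, which were singled out from it afterwards and so are no evidence apart from it. Its 21 measured members had a median of -0.29 at 6 h (central random range -0.25 to 0.04, percentile 1.13) and -0.43 at 24 h (percentile 0.07). After quantile normalization the median at 24 h was -0.22 (range -0.11 to 0.21). This cannot decide on scaling, which moves a list and its level-matched random lists alike. The 10 members with a mean log2 signal below 8 had a median of -0.72 at 24 h, below equally dim random lists (-0.50 to 0.20), but the 11 brighter members had -0.21, inside their range of -0.31 to 0.04. The pattern as a list may therefore rest on its dim members alone. With 1 array per time and 0 untreated arrays at a treated time, the candidate explanation stays a hypothesis.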
